A study of Drosophila melanogaster with 18 samples.

How the data were processed

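Total RNA from 2 Drosophila melanogaster cell lines, R3 and R7, was measured on 18 Affymetrix 3' expression arrays, 9 per line. Passage numbers were taken from the labels. The labels name 3 stages, early, intermediate and late, and passage 4 lies in the passage range of both early and intermediate. R3 contributed 2 early arrays (both P2), 4 intermediate arrays (P5, P6, P7 and P8) and 3 late arrays (P16, P17 and P19). R7 contributed 3 early arrays (P2 in 2 replicates and P3), 1 array at P4 that was kept as a group of its own, 2 intermediate arrays (P7 and P8) and 3 late arrays (P16, P17 and P19). Successive passages of 1 culture stand in for replicates, so every p-value measures the spread between passages and arrays, not between independent cultures.

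The deposited values are intensity on a linear scale, 1 per probe set, already summarised and scaled between arrays by the authors. The method of summarisation and scaling is not stated in the labels used here. The table holds 18952 probe sets, of which 183 are controls, and its values run from 0.82 to 14634. Array medians lay between 23.2 and 30.4 and 2% trimmed means between 199 and 223. The ratio of 3' to 5' probe sets lay between 1.14 and 1.35 for GAPDH and between 1.64 and 2.29 for actin. For arrays, precision is limited by their number.

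Values below 32 were set to 32 before log2. This floor was chosen from the difference between the 2 R7 P2 replicates, whose SD was 0.853 (log2) for probe sets below an intensity of 16, 0.421 from 16 to 32, 0.273 from 32 to 64 and 0.0784 above 1024. Between 44.1% and 48.9% of the 18769 non-control probe sets lay above the floor on each array, and 7951 lay above it on no array. The 10200 probe sets above the floor on at least 2 arrays were tested. A fold against a group whose arrays all lie at the floor is a lower bound and is written "at least".

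Gene names came from the array's annotation and were updated through Entrez gene numbers. Of the non-control probe sets, 13647 had exactly 1 symbol, 402 had several and 4720 had none. The annotation held 11982 genes, and 7929 genes had a tested probe set. Some genes planned for naming, among them Mef2, Myc, Ras85D, roX1, roX2 and CG9650, had no probe set named here and were not analysed.

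Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit of the 18 arrays and 7 groups, with 11 residual degrees of freedom. Benjamini-Hochberg adjustment ran over the tested probe sets, and a probe set was called at an adjusted p under 0.05. A separate limma fit had 1 slope on log2 of the passage number per line. Standard errors are limma's. Groups are given as mean intensity as deposited, with the SD over the arrays.

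The 30 gene lists (cell type markers, pathways and processes) were fixed before the data were examined, as were the comparisons, the rule for named genes and all alternatives except those said to be chosen after seeing the data. Of these, 28 had the minimum of 5 tested members. They were tested on 1 probe set per gene with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists. They were tested again with an estimated correlation and with fry (statmod 1.5.0). The fry results are not given here. The list of adult muscle precursor markers was written knowing that the study named this cell type from these samples. Synexpression of a list was the mean pairwise Pearson correlation of its members over the 18 arrays after subtracting each line's mean, as a percentile among 10000 random lists of equal size matched on mean expression.

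Genes were named by rule, with 1 probe set per gene (the highest mean among those with exactly 1 symbol). The rule took the 10 largest rises and falls from early to late called in R3, in R7 and in the mean of the lines with no overlap of arrays. It also took the 6 largest in each direction for the interaction and for R7 minus R3 late, and the 5 with the largest smaller step for genes that peak or dip at the intermediate stage. Up to 4 members of each list with the smallest adjusted p in the mean of the lines, the muscle precursor markers and Sxl completed it. A further condition, a group mean above the median of all values, removed nothing because that median, 26.0, lies below the floor. The rule's first part named 0 genes with the labels as given. It was therefore applied, after seeing the data, to R7 alone and to a fit without 2 R3 arrays.

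Alternatives were quantile normalization, equal array medians, a filter leaving out the 30% dimmest tested probe sets, an intensity trend with a robust prior, 1 probe set per gene, P4 counted as early or as intermediate, early arrays at P2 only, fits of the compared arrays alone, a replicate block, a 2-fold minimum, linear passage, median absolute differences, line means kept, and leaving out each array in turn. After seeing the data, the floors of 16 and 64 were chosen, and fits were added without the arrays labelled R3 P2 replicate 2 and R3 P19 (the fit without 2 R3 arrays) and without these and the array labelled R3 P8 (the fit without 3 R3 arrays). In both of these fits R3 early is a single array, which is assumed to vary like the other groups.

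The test of R7 late minus early was checked on simulated data over 10200 probe sets. The simulation used independent normal noise with each probe set's residual SD in the fit of all 18 arrays. Changes were planted in R7 late only for probe sets whose mean lay more than 4-fold above the floor. Recovery nearer the floor was not simulated. The test recovered 46.3% of 67 changes of 1.5-fold, 83.6% of 67 changes of 2-fold and 93.9% of 66 changes of 4-fold, and 12 of 161 calls were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.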

Results

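Expression was measured along the passage series of 2 Drosophila cell lines, R3 and R7, as each went from early culture to an established line. R3 had 2 early, 4 intermediate and 3 late arrays. R7 had 3 early, 2 intermediate and 3 late arrays and 1 array at P4. The series was made to find genes expressed together over time during immortalization and signatures of progenitor cells.

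Among the genes the rule took from R7, Hs3st-A and Kr had the largest rises from early to late passages and CG31676 the largest fall. Hs3st-A (Entrez gene 37161), which encodes a heparan sulfate 3-O-sulfotransferase, rose from an intensity of 22.2 ± 5.02 (SD, n = 3 arrays) to 2180 ± 185 (n = 3), at least 68.0-fold (log2 6.09 ± 0.59 SE, limma adjusted p = 2.3e-05). The zinc finger transcription factor gene Kr (Entrez gene 38012) rose 32.8-fold, from 44.5 ± 6.08 to 1459 ± 220 (adjusted p = 3.3e-05). The genes fred and opa, the latter encoding a zinc finger transcription factor, rose at least 14.4-fold and at least 14.0-fold, and orb, an RNA-binding translational regulator, rose 13.7-fold. CG31676 (Entrez gene 35351) fell at least 149-fold, from 4784 ± 237 to 22.9 ± 5.45 (adjusted p = 0.0102), and CG1208 (Entrez gene 40727) fell at least 66.1-fold (adjusted p = 0.00496).

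Of the other genes taken from R7, Tsp5D, which encodes a tetraspanin, rose 13.6-fold, and Epac, an exchange factor activated by cyclic AMP, rose 10.7-fold. CG43102 rose at least 12.8-fold, cona 12.5-fold and CG4666 11.0-fold. Nplp2 fell 37.7-fold, and apolpp, the precursor of the main haemolymph lipid carrier, fell at least 27.5-fold. CG34166, IM33, CG8157, CG15369, Hesr and CG1468 fell at least 28.4-fold each, to the floor in all 3 late arrays. In these 20 genes the 3 early and 3 late arrays did not overlap, as the rule requires. The calls of 6 of them were lost with 1 array left out. Without R7 P2 replicate 1 the adjusted p of CG34166, CG8157, CG1468, cona and IM33 lay between 0.0522 and 0.0727. Without R7 P2 replicate 2 it lay between 0.0531 and 0.0820 for these and Hesr. Without R7 P16 it was 0.0526 for cona and 0.0570 for IM33, without R7 P17 0.0644 and 0.0527, and without R7 P19 it lay between 0.0505 and 0.0749 for cona, IM33, CG8157, CG1468 and Hesr. With P4 counted as early, CG1468 (0.0904), CG15369 (0.0755) and CG8157 (0.0581) were not called.

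In R7, 892 probe sets were higher and 1139 lower in late than in early arrays, of 10200 tested, and 675 of these 2031 changed at least 2-fold. The share of calls that were higher, 43.9%, depended on the scaling: it was 64% after quantile normalization and 71.4% with equal array medians. The median change of all tested probe sets was -0.03 (log2) as deposited and 0.155 with equal medians. Array medians lie below the floor of 32, at 27.7 to 30.4 in R7 early and 23.2 to 26.3 in R7 late. Equal medians therefore scale on weak signal and raise late values against early ones in R7. Without the array labelled R7 P19 the count was 995, without R7 P2 replicate 2 it was 1053, without R7 P2 replicate 1 it was 1223, and without R7 P16 it was 1305. All 7 groups share 1 estimate of the spread per probe set, so the R3 arrays also enter the R7 p-values. Without R3 P19 the R7 count was 2594.

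Of the neuroblast markers, 7 of 10 tested members fell in R7 and 1 rose. Adjusted over the list alone, 8 fell and 1 rose. The proneural gene ase fell 2.30-fold, pros and grh, which encode transcription factors of neural lineages, fell at least 2.50-fold and at least 2.96-fold, and sna, also a mesoderm regulator, fell at least 1.56-fold. Mean intensities in R7 early were 75.4 for ase, 81.6 for pros, 94.8 for grh and 50.1 for sna. The other members that fell were wor, dpn and insc, with 62.5, 63.2 and 238. Apart from insc, these early means lay near the floor, so the falls started from weak signal. The member that rose was brat, a repressor of neuroblast self-renewal. The list was lower than other genes (camera adjusted p = 0.00100), with adjusted p = 0.409 with an estimated correlation, and it was not called at a floor of 64 (adjusted p = 0.162, range over the alternatives 1.33e-05 to 0.409).

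Of the Imd and Toll innate immunity genes, 8 of 16 fell and 0 rose in R7. Adjusted over the list alone, 9 fell. Tl, which encodes the Toll receptor, fell 3.94-fold, from 839 ± 84.7 (SD, n = 3) to 222 ± 87.0 (n = 3, limma adjusted p = 0.00362). The list was lower than other genes (camera adjusted p = 0.00603), with adjusted p = 0.732 with an estimated correlation. It was not called without the dimmest 30% (0.0633, range over the alternatives 4.5e-05 to 0.732).

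Of the haemocyte markers, 8 of 20 fell and 0 rose in R7. Adjusted over the list alone, 8 fell and 1 rose. He, which encodes a haemocyte surface protein, fell 23.4-fold, from 1967 ± 909 (SD, n = 3) to 77.6 ± 18 (n = 3, limma adjusted p = 0.0111). The phagocytosis receptor gene NimC1 fell 5.83-fold, and Ppn, an extracellular matrix protein made by haemocytes, fell 5.19-fold. The camera adjusted p was 0.0367, with adjusted p = 0.752 with an estimated correlation. The list call was lost without R3 P2 replicate 1 (0.0506), R3 P2 replicate 2 (0.0503), R3 P19 (0.0552), R7 P2 replicate 1 (0.0919), R7 P2 replicate 2 (0.138), R7 P16 (0.0518) or R7 P19 (0.132). It was also lost with P4 as early (0.337), without the dimmest 30% (0.0563), with the compared arrays alone (0.0553), at a floor of 64 (0.0520) and without 2 R3 arrays (0.0636; range 0.000377 to 0.752).

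Of the Notch list, which holds components of the pathway beside its targets, 7 of 12 fell and 1 rose in R7 (7 and 2 adjusted over the list alone). E(spl)mbeta-HLH, a transcriptional repressor induced by Notch, fell 2.67-fold, and fng, a glycosyltransferase that modifies Notch, fell 2.27-fold, while kuz, a protease that cleaves Notch, rose 1.63-fold. The camera adjusted p was 0.0367, with adjusted p = 0.659 with an estimated correlation. The list was not called without R7 P3 (0.233), R7 P16 (0.0715) or the dimmest 30% (0.0633), nor at a floor of 16 (0.0583; range 0.000778 to 0.659).

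Of the imaginal disc patterning genes, 3 of 9 fell and 0 rose in R7, also when adjusted over the list alone: dpp, a BMP-type morphogen, fell at least 3.04-fold, salm, a transcription factor downstream of it, at least 4.63-fold, and bi 4.56-fold. The camera adjusted p was 0.0367, with adjusted p = 0.659 with an estimated correlation. The list was not called without R7 P3 (0.212) or R7 P16 (0.0678), nor at a floor of 64 (0.0590; range 0.000778 to 0.659).

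Of the glycolysis genes, 4 of 10 fell and 0 rose in R7, also when adjusted over the list alone. Tpi, Pgi and Pfk encode glycolytic enzymes and Pepck1 an enzyme of gluconeogenesis. Each of these 4 calls was lost in at least 4 of the fits without 1 R7 early or late array, with adjusted p up to 0.175 for Pgi and 0.142 for Pfk, both without R7 P19. The camera adjusted p was 0.0367, with adjusted p = 0.749 with an estimated correlation. The list was not called without R7 P3 (0.202) or R7 P19 (0.0956).

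**Figure D1:**
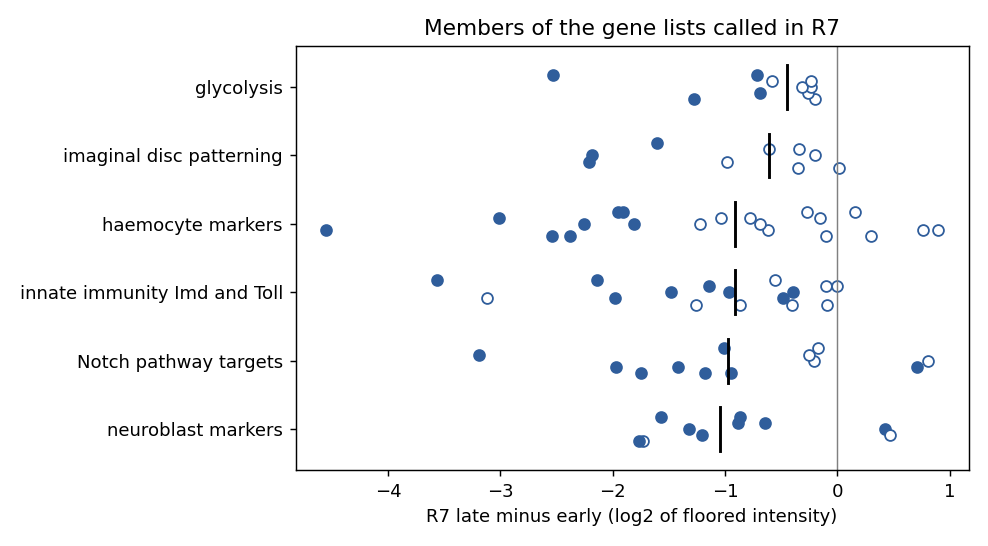
R7 late minus early (log2 of floored intensity, horizontal axis) of each tested member of the 6 gene lists called in R7. Neuroblast markers had 7 of 10 members lower and 1 higher, and haemocyte markers 8 of 20 lower and 0 higher.

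The other 22 tested lists were not called in R7. Of the adult muscle precursor markers, chosen knowing that the study named this cell type from these samples and so not independent evidence, 1 of 6 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.613). The mesoderm regulator gene twi rose, from 1035 ± 223 to 1954 ± 295, and Him fell 9.15-fold, while zfh1, htl, ct and vg were not called. The Him call was lost without R7 P2 replicate 1 (0.0548), R7 P2 replicate 2 (0.0555), R7 P3 (0.0587), R7 P16 (0.0719), R7 P17 (0.0518) or R7 P19 (0.0534). Early mesoderm genes had 4 of 10 lower and 1 higher (adjusted p = 0.151), DNA replication genes 2 of 33 higher and 0 lower (0.151), and ribosome biogenesis genes 1 of 18 higher and 1 lower (0.958). The early mesoderm list was called lower with equal medians (0.0122) and without 3 R3 arrays (0.0350; range over the alternatives 0.0122 to 0.959). DNA replication genes were called without R7 P17 (0.00630) and with P4 as early (0.0319; range 0.00630 to 0.862), and fat body markers, with 3 of 9 lower and 0 higher (adjusted p = 0.273), without R7 P3 (0.0178) and with equal medians (0.0473; range 0.0178 to 0.752). The sarcomere and other muscle structural genes had 3 of 18 lower and 1 higher (0.686). The median, mean and test differed in sign for the adult muscle precursor list (median 0.11, mean -0.31, test up), basement membrane (0.16, -0.21, up), Ras/MAPK (0.02, -0.01, up), dosage compensation (0.03, -0.16, up), piRNA (0.05, -0.15, up) and ribosome biogenesis (-0.04, -0.02, up) lists. For the neuron and ecdysone lists the median was 0, the mean negative and the test up. Hox genes and midgut markers had 3 tested members each, too few for the list test. Dfd, Scr and Antp, which specify head and thorax segments, had means of 178 ± 74.2, 210 ± 26.6 and 103 ± 29.1 in R7 early and fell at least 5.26-fold, 6.54-fold and 3.13-fold. The Antp call was lost without R7 P2 replicate 2 (0.0534).

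In R3, 0 probe sets were called between late and early arrays by limma, and 613 had a raw p under 0.05. The arrays labelled R3 P2 replicate 2 and R3 P19 differed from the other arrays of their stage. CG31676 had 6913 in R3 P2 replicate 1 and 463 in R3 P2 replicate 2, and 35.1, 43.4 and 6765 in R3 P16, P17 and P19. Hand (Entrez gene 34379), which encodes a transcription factor of heart and blood progenitors, had 1698 and 12.2 in the 2 P2 replicates and 8.72, 10.5 and 1713 in the late arrays. Without R3 P19 alone 117 probe sets were called, and without R3 P2 replicate 1 alone 65.

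Without both arrays, a fit chosen after seeing the data in which R3 early is 1 array, 389 probe sets were higher and 630 lower in R3 late than early. Without R3 P8 as well, these were 425 and 639. In the fit without 2 R3 arrays, 176 probe sets rose and 387 fell in both lines, against 51.2 and 104 expected for independent lists, while 0 were shared by limma's calls with all 18 arrays, 56 without R3 P19 alone and 13 without R3 P2 replicate 1 alone. That expectation takes the calls of the lines as unrelated, but both share 1 estimate of the spread per probe set. This alone can raise the overlap above it. The genes taken by the rule from this fit included Hs3st-A (at least 4.24-fold in R3) and firl (40.2-fold) among those that rose. CG31676 (177-fold), Hand (at least 53.1-fold) and Hesr (at least 35.1-fold) were among those that fell in R3. In this fit, mitochondrial respiration genes were lower in R3 late, with 4 of 16 lower and 0 higher (10 lower adjusted over the list alone, camera adjusted p = 0.000490, adjusted p = 0.727 with an estimated correlation). Basement membrane genes were higher, with 6 of 17 higher and 1 lower (6 and 2 adjusted over the list alone, 0.0485, adjusted p = 0.727 with an estimated correlation).

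**Figure D2:**
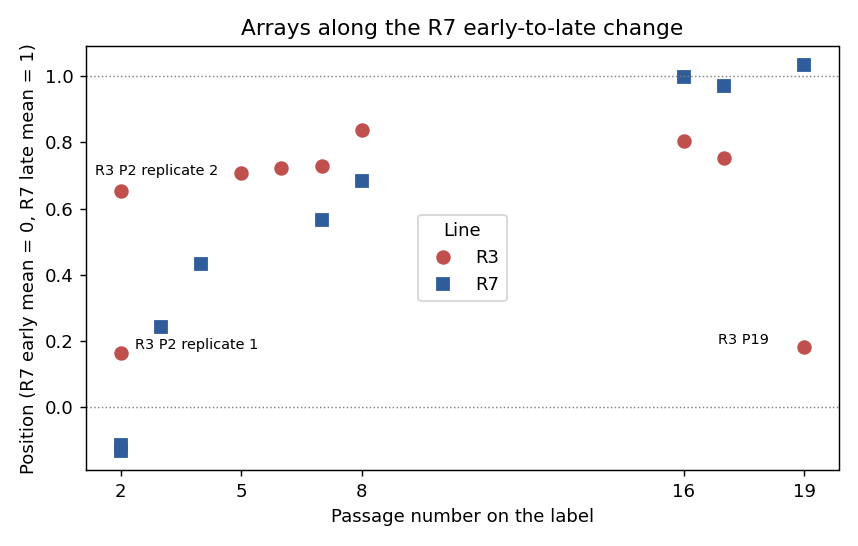
Position of each array on the axis of the 675 probe sets that changed at least 2-fold between R7 early (0) and R7 late (1), against passage number. The arrays labelled R3 P2 replicate 1 and R3 P19 lay at 0.165 and 0.182 and the other R3 arrays between 0.654 and 0.837.

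In the mean of both lines, opa rose 3.44-fold (log2 1.78 ± 0.14 SE, limma adjusted p = 1.8e-05), fred 3.07-fold and orb 2.98-fold from early to late. R7 carried these means: the R3 values were -0.25, -0.62 and -0.63 (log2) and were not called. Act79B, an actin of adult muscle, fell 4.10-fold (adjusted p = 0.00386). Neuroblast markers had 4 of 10 members lower and 0 higher (8 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000823, adjusted p = 0.386 with an estimated correlation). R7 carried this call too, since dpn, grh, pros, sna and wor, 5 of the 7 members lower in R7, lay at the floor on every R3 early and late array. Glycolysis genes had 3 of 10 lower and 0 higher (8 lower adjusted over the list alone, 0.00147, adjusted p = 0.863 with an estimated correlation). Imd and Toll genes had 2 of 16 lower and 0 higher (7 lower adjusted over the list alone, 0.0217, adjusted p = 0.863 with an estimated correlation). With an estimated correlation, 0 lists were called here and 0 in R7. Median, mean and test differed in sign for the adult muscle precursor, fusion, germline, mitochondrial respiration, piRNA and ribosome biogenesis lists.

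In this comparison, 357 probe sets were higher and 562 lower, and 210 changed at least 2-fold. The share that was higher was 38.8%, against 66.1% after quantile normalization and 52.9% with equal medians. The count was 2127 without R3 P19, 419 without R3 P16, 420 without R3 P17, 435 without R7 P19, 458 without R7 P2 replicate 2 and 481 without R7 P2 replicate 1. The glycolysis call was lost without R3 P2 replicate 2 (0.0774), without 2 R3 arrays (0.170) and without 3 (0.179; range over the alternatives 1.4e-06 to 0.863), and the Imd and Toll call without R3 P2 replicate 1 (0.105), R7 P2 replicate 2 (0.0705) or R7 P19 (0.0735). The latter was also lost without the dimmest 30% (0.235), with P4 as early (0.0930), at a floor of 64 (0.0944) and without 3 R3 arrays (0.0557; range 0.000396 to 0.863). The neuroblast call was lost at a floor of 64 (0.224) and without 3 R3 arrays (0.0557; range 7.2e-06 to 0.386). The disc list was called with equal medians (0.0119) and at a floor of 16 (0.0493; range 0.0119 to 0.863), the Notch list without 2 R3 arrays (0.0483; range 0.0483 to 0.863), and DNA replication also with P4 as early (0.0201; range 0.00244 to 0.863). DNA replication genes were called without R3 P2 replicate 1 (0.00608), R3 P19 (0.0255), R7 P2 replicate 1 (0.0365) or R7 P17 (0.00244).

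The change from early to late differed between the lines for 297 probe sets, 168 higher and 129 lower in R7 minus R3. These were 291 and 130 after quantile normalization and 387 and 83 with equal medians. Kr had the largest difference upward (log2 6.23 ± 0.76 SE, limma adjusted p = 0.000635), with means of 559 ± 566 (SD, n = 2) and 180 ± 77.6 (n = 3) in R3 early and late. Hs3st-A (5.88), fred (4.47), CG15236 (4.47), orb (4.41) and CngA, a cyclic nucleotide-gated channel subunit (4.28), followed. The R3 side of the interaction includes the arrays labelled R3 P2 replicate 2 and R3 P19, which lay apart from their stage. The R3 change of Kr was -1.20 (log2, not called) as given. Without these 2 arrays, where R3 early is 1 array, it was 0.23. Downward differences included CG15554 (-4.01), at the floor in all R3 groups, and CG32816 (-3.59). Haemocyte, neuroblast, disc, Notch and Imd and Toll lists were lower in R7 minus R3 (camera adjusted p = 0.00437, 0.000523, 0.0465, 0.00437 and 0.0114). These had adjusted p = 0.580, 0.340, 0.430, 0.430 and 0.580 with an estimated correlation. Over all genes 1, 4, 0, 1 and 0 members were lower, and adjusted over the list alone 2, 6, 2, 4 and 0 were. For the neuroblast list this largely repeats the R7 change, since the 5 members at the floor in R3 could not fall there. The count of probe sets was 671 without R7 P3, 599 without R3 P2 replicate 1, 136 without R3 P2 replicate 2, 179 without R7 P2 replicate 2 and 184 without R7 P19.

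**Figure D3:**
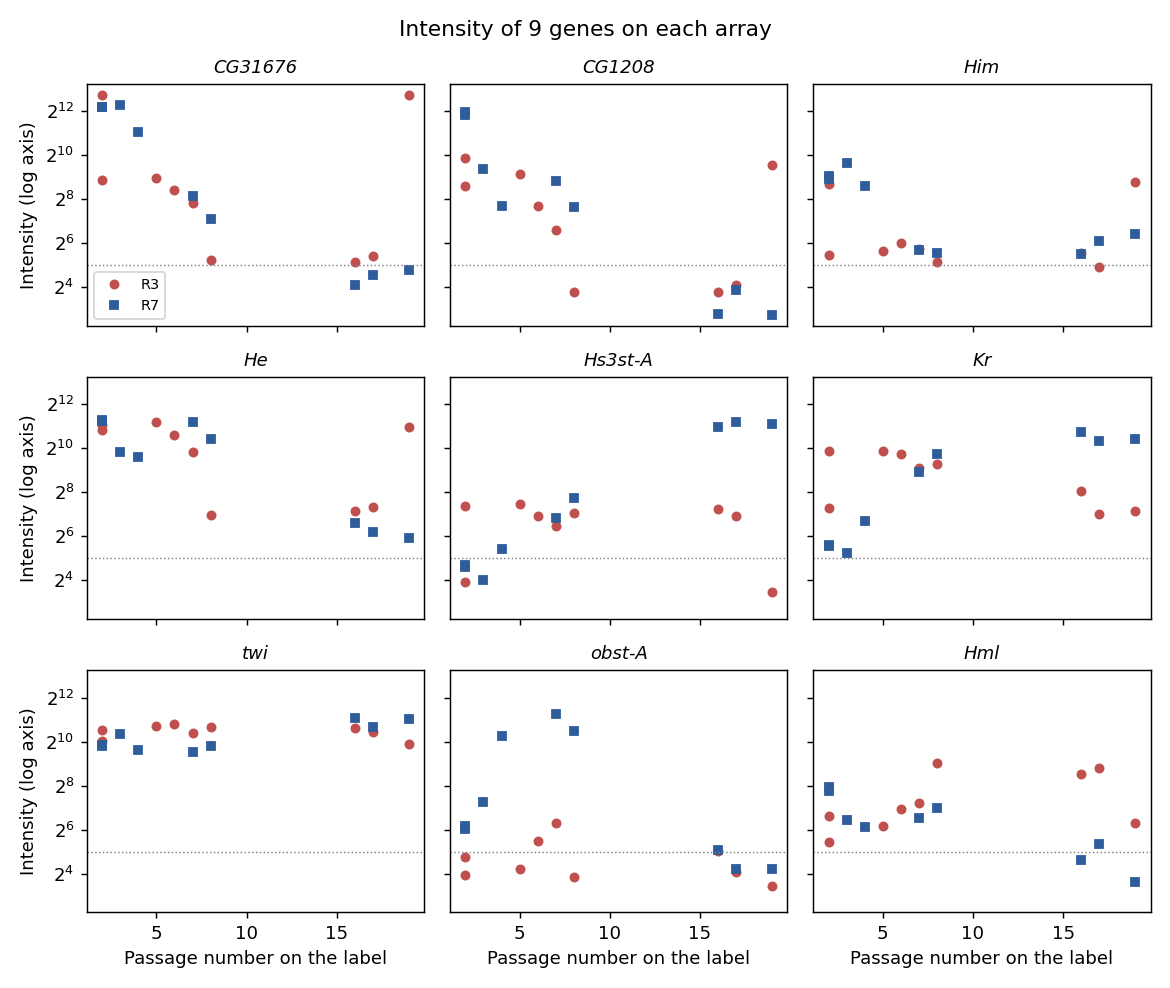
Intensity (log axis) of 9 genes against passage in both lines, with the floor of 32 dotted and values below 1 drawn at 1. In R7, Hs3st-A rose to 2180 and CG31676 fell to 22.9 in the mean of the R7 late arrays.

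In late arrays, R7 exceeded R3 in Hs3st-A (25.9-fold, log2 4.70 ± 0.59 SE, limma adjusted p = 0.000404), in mid, a T-box transcription factor gene (at least 17.5-fold), and in fred (at least 14.4-fold), opa (14.0-fold), CG15236 (12.6-fold) and orb (12.1-fold). R7 was lower than R3 in CG9691 (10.5-fold), CG13403 (9.59-fold) and CAH2, which encodes a carbonic anhydrase (at least 6.57-fold). R3 late includes the array labelled R3 P19, which lay apart from the other R3 late arrays. Of the 778 probe sets called, 538 were higher and 240 lower in R7. These were 632 and 233 after quantile normalization, 511 and 129 with equal medians, 603 and 526 without 2 R3 arrays and 608 and 534 without 3. Epithelial junction genes were lower in R7, with 1 of 15 lower and 0 higher (7 lower adjusted over the list alone, camera adjusted p = 0.00374, adjusted p = 0.726 with an estimated correlation). Glycolysis genes had 1 of 10 lower and 0 higher (3 lower adjusted over the list alone, 0.00374, adjusted p = 0.726 with an estimated correlation). Basement membrane genes had 4 of 17 lower and 0 higher (4 lower adjusted over the list alone, 0.0412, adjusted p = 0.768 with an estimated correlation). The count was 370 without R7 P19. R7 minus R3 gave 98 higher and 11 lower probe sets in early arrays and 167 and 25 in intermediate arrays. Without 2 R3 arrays these were 95 and 75 early and 278 and 114 intermediate, and without 3 they were 91 and 71 and 244 and 106. The early count was 408 without R7 P3 and 174 without R3 P2 replicate 1, and the intermediate count was 92 without R7 P7.

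Between early and intermediate arrays R7 changed in 125 probe sets upward and 128 downward, against 200 and 101 after quantile normalization and 151 and 80 with equal medians. Haemocyte, neuroblast, JAK/STAT and Imd and Toll genes were lower as lists (camera adjusted p = 0.00590, 0.00590, 0.0253 and 0.00587). These had adjusted p = 0.571, 0.550, 0.550 and 0.563 with an estimated correlation. Over all genes 0, 3, 0 and 0 members were lower, and adjusted over the list alone 4, 7, 3 and 8 were. Between intermediate and late arrays 206 probe sets rose and 271 fell in R7, against 278 and 243 after quantile normalization and 164 and 200 with equal medians. There cuticle (4 of 12 lower), disc (3 of 9) and glycolysis (1 of 10) genes were lower. Their camera adjusted p was 0.00413, 0.0253 and 0.00413, with adjusted p = 0.288, 0.464 and 0.650 with an estimated correlation, and 4, 3 and 3 members were lower adjusted over the list alone. The early to intermediate count was 855 without R7 P3, 603 without R3 P19, 404 and 402 without the R3 P2 replicates, 148 and 147 without the R7 P2 replicates, 132 without R7 P8 and 128 without R7 P7. The intermediate to late count was 137 without R7 P7, 301 without R7 P8, 247 without R7 P19 and 645 without R3 P19. In R3, limma called 0 probe sets in both steps, with 730 and 425 at a raw p under 0.05. Without R3 P2 replicate 2 the first step had 14, and without R3 P19 the second had 7.

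In the mean of the lines, 44 probe sets peaked and 6 dipped at the intermediate stage. Without 2 R3 arrays 80 peaked and 35 dipped, and without 3 it was 93 and 62. The total of 50 was 9 with P4 counted as early, 6 without the dimmest 30% and 15 at 2-fold or more. The chitin-binding protein gene obst-A had 96.5 ± 48.8 (SD, n = 3) in R7 early, 1934 ± 711 (n = 2) in R7 intermediate and 23.7 ± 8.81 (n = 3) in R7 late arrays. CG3823, the chitin deacetylase gene Cda4 and the cuticle protein gene Cpr78E also peaked. R7 carried these 4 peaks: the highest R3 array had 79.3 for obst-A, 36.2 for CG3823, 20.1 for Cda4 and 33.0 for Cpr78E. For obst-A, CG3823 and Cda4 the rise was not called with P4 counted as early (adjusted p = 0.146, 0.138 and 0.161), and for Cpr78E with P4 counted as intermediate (0.127). Without R3 P2 replicate 2 the count was 88, without R3 P2 replicate 1 it was 29 and without R7 P7 it was 30.

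A slope on log2 of the passage number was called for 0 probe sets in R3 by limma, with 582 at a raw p under 0.05, and for 2000 in R7, 873 rising and 1127 falling. Without R3 P19 alone 151 were called in R3, and without R3 P2 replicate 1 alone 19. In R7 the count was 1179 without R7 P2 replicate 2, 1191 without R7 P19 and 1324 without R7 P2 replicate 1. The late minus early changes of R3 and R7 had a Pearson correlation of 0.397 and a Spearman correlation of 0.245 across probe sets, which are not independent replicates. Pearson's value was -0.148 without R3 P2 replicate 1 and 0.642 without R3 P2 replicate 2. The SD between the lines at matched passages was 0.501 at P2, 0.478 at P7, 0.471 at P8, 0.453 at P16, 0.466 at P17 and 0.755 at P19 (log2).

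Members of 15 of 28 lists were correlated over the 18 arrays above the 95th percentile of random lists. Glycolysis (mean r 0.648), mitochondrial respiration (0.602), haemocyte (0.354) and DNA replication (0.343) genes lay above all random lists. Heat shock (0.450), Imd and Toll (0.370) and ribosome biogenesis (0.284) genes were also above the 95th percentile. The adult muscle precursor markers (0.0788) lay at the 77.5th percentile. With array medians equalised 5 lists passed.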

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

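The weighing of the 3 patterns and all counts over other splits of the samples used tests chosen after the results were seen, while the comparisons they concern were planned.

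The arrays labelled R3 P2 replicate 2 and R3 P19 lay apart from the other arrays of their stage: R3 P19 was nearest to R3 P2 replicate 1 (r = 0.994 across probe sets) and R3 P2 replicate 2 to R3 P6 (0.990). An exchange of these 2 labels is argued against, since the array labelled R3 P2 replicate 2 lay at -0.0135 on the axis from the R3 P5 to P7 mean (0) to the R3 P16 and P17 mean (1). The array labelled R3 P8, an intermediate array, lay at 0.852 on this axis and was nearest to R3 P16 (r = 0.995). Labels of the 8 R3 arrays after P2 replicate 1 displaced by 1 place may account for the pattern: displaced, the mean SD between the lines at matched passages was 0.438, against 0.521 as given and 0.464 for the lowest of the other rotations. A return of the culture to its early profile at P19 stays open: the SD of 0.229 between R3 P19 and R3 P2 replicate 1 restates the pattern, and a return leaves the SD of 0.645 between the R3 P2 replicates (0.151 in R7) unaccounted for. Both are hypotheses found on these data, and no group was reassigned.

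In R7, 8 of 20 haemocyte and 7 of 10 neuroblast members fell from early to late (adjusted p = 0.752 and adjusted p = 0.409 for the lists with an estimated correlation), and 1 loss of other cell types from the culture could be expected to lower both at the same passages. At P7 and P8 the called haemocyte members had completed a median of 56.6% of their fall (n = 8) and the neuroblast members 100% (n = 7), with wor, pros, sna and dpn already below the floor, and a two-sided exact permutation test of the difference gave p = 0.141, which decides nothing. The share is measured from an early mean that includes P3, where the median of all 20 haemocyte members against R7 P2 replicate 1 was already -1.47 (log2), beside -2.44 at P4, -1.37 and -1.42 at P7 and P8 and -1.46, -1.11 and -2.37 at P16, P17 and P19, while that of all 10 neuroblast members was -0.45 at P3, -1.05 at P4, -1.35 and -1.23 at P7 and P8 and -1.38, -1.48 and -1.48 late, so the order of the lists depends on the measure. Single members did not follow a common course: grh had 94.8 in early, 319 in intermediate and 15.7 in late arrays, and He had 1967, 1849 and 77.6. As grh is also among the 53 genes that peaked in R7, its course may not track that of the other neuroblast members. A loss of haemocyte-like cells also stays open, with an SD of 0.898 for the log2 falls and 33.6 percentage points for the shares, and changed expression within the cells was not tested.

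In R7, 53 genes peaked and 8 dipped at P7 and P8, and obst-A, Cda4 and Cpr78E were singled out among the peaks after their values were seen. Against the mean of early and late arrays, the fixed cuticle list, which holds only obst-A of these, was higher with 1 of 12 members peaking (limma's camera adjusted p = 0.00403), with adjusted p = 0.219 with an estimated correlation. A larger share of epithelial cells or an ecdysone response might raise such genes. The same test gave adjusted p = 0.937 (unadjusted 0.870) for the epithelial list and adjusted p = 0.221 (unadjusted 0.111) for the ecdysone list, which decides neither, so both explanations stay open.

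The change with passage differed between the lines by a test of the interaction for 12 genes taken by the rule. Its R3 side includes the arrays labelled R3 P2 replicate 2 and R3 P19, which lay apart from their stage. R7 minus R3 was 6.23 for Kr, 5.88 for Hs3st-A, 4.47 for fred, 4.47 for CG15236, 4.41 for orb and 4.28 for CngA (log2). It was -4.48 for CG9691, -4.01 for CG15554, -3.97 for CG34232, -3.88 for CG13403, -3.59 for CG32816 and -3.41 for CAH2. Without R3 P2 replicate 2 the adjusted p was 0.108 for CG9691, 0.121 for CG34232, 0.0839 for CG13403 and 0.0660 for CAH2. CG9691 was also lost without R7 P2 replicate 2 (0.0532) or R7 P19 (0.0542). CG34232 was lost as well without R3 P16 (0.0533), R3 P17 (0.0633), R7 P2 replicate 1 (0.0593), R7 P2 replicate 2 (0.0774), R7 P17 (0.0516) or R7 P19 (0.0742). The same test on lists gave camera adjusted p = 0.00437 for haemocyte, 0.000523 for neuroblast, 0.0465 for disc, 0.00437 for Notch and 0.0114 for Imd and Toll genes. In that order these had adjusted p = 0.580, 0.340, 0.430, 0.430 and 0.580 with an estimated correlation. Of the neuroblast members, dpn, grh, pros, sna and wor lay at the floor in R3 and could not fall there.

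In R3 intermediate, 1 array lay far from the other 3 relative to the range of the values for 7 of 115 genes, where chance gives about 5.75. The distances were small for some: the fold to the nearest array ran from 1.07 for Polr1A to 2.87 for CG9691. The gap to the nearest array as a share of the range was 0.878 for CG15236 in R3 P6, 0.830 for CG3703 in R3 P5, 0.856 for CG9691 in R3 P8, 0.942 for Polr1A in R3 P5, 0.955 for Tret1-1 in R3 P7, 0.949 for apolpp in R3 P5 and 0.830 for moon in R3 P8.

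Other splits of the samples were counted for comparisons of at least 3 arrays a group and, within the lines, for results that combine both lines, where R3 early and R7 intermediate hold 2 arrays each. The 10 splits of 3 against 3 arrays are too few for a share under 0.05. For R7 late minus early, 1 of 10 splits called as many (2031 in the fit of all 18 arrays, highest other 1). For the R7 lists 3 of 10 did (6, highest other 7), and for R7 minus R3 late 1 of 10 (778, highest other 2). Chance was not excluded for the mean of the lines (919, highest other 3568; 6 of 100) or its lists (3, highest other 12; 72 of 100). For the interaction 21 of 100 splits called as many (297, highest other 3568), which decides nothing. Some splits keep the R7 early and late arrays together and exchange their labels, which turns the mean of the lines into the interaction and the reverse. With R3 as given, such a split called 297 for the mean and 919 for the interaction. The shares for both results therefore include the real R7 change. Where the real count is 0, every split calls as many by construction and the count of splits says nothing: R3 late minus intermediate (0, highest other 135; 35 of 35 splits) and probe sets called in both lines (0, highest other 931; 100 of 100). The split with 3568 for the mean put R3 P19 in the place of R3 P2 replicate 2, which points to a structure of the samples. The split with 3568 for the interaction did so too and also exchanged the R7 early and late labels. For the intermediate stage apart from early and late, 2 of 100 splits called as many with the arrays grouped as described (50, highest other 228). This cannot exclude chance, since another split called 228 and successive passages of 1 culture are not interchangeable. The count of 50 was 9 with P4 counted as early and 6 without the dimmest 30%, and no splits were counted under those settings.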

How the results depend on the processing

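The floors of 16 and 64 and the fits without 2 and 3 R3 arrays were chosen after seeing the data, and the other alternatives were planned. With 1 probe set per gene and at a floor of 16, none of the 25 comparison results moved beyond the tolerance set for it. For counts this tolerance is on their size and tests neither direction nor side of the threshold. At a floor of 16, 1 count by direction moved. There 1 list call was lost (Notch, in R7) and 1 gained (disc, in the mean of the lines). Unless said otherwise, the cause was not tested. Signal near the floor limits folds to lower bounds.

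With quantile normalization R3 intermediate minus early called 2 probe sets, with a trend and robust prior 1, and with a replicate block 2. With medians equalised the interaction called 470 and 5 lists passed for synexpression. Leaving out the lowest 30%, the interaction called 176, R7 intermediate minus early 41, R7 late minus intermediate 271, R7 minus R3 early 24 and intermediate 68, the intermediate stage apart 6, and 1 list each in R7 and in the mean of the lines (glycolysis). There Imd and Toll genes were lost in both and haemocyte and Notch genes in R7, and the neuroblast and disc lists kept too few tested members to be tested. With P4 as early, R7 intermediate minus early called 43, R7 minus R3 early 42 and intermediate 122, and the stage apart 9. With P4 as intermediate, R7 intermediate minus early called 418 and late minus intermediate 952. With P2 only, the interaction called 671, R7 intermediate minus early 855 and R7 minus R3 early 408. With the compared arrays alone, where fewer arrays enter the fit, the mean of the lines called 353, the interaction 124, and R7 minus R3 early 1 and late 192.

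At 2-fold or more, fewer by construction, 675 were called in R7 late minus early, 210 in the mean, 166 in the interaction, 138 and 249 in the R7 steps from early and to late, 71, 120 and 205 in R7 minus R3 early, intermediate and late, and 15 apart. With an estimated correlation 0 and 0 lists were called. As a median absolute difference, the spread between the lines was 0.126 at P2, 0.167 at P7, 0.139 at P8, 0.169 at P16, 0.179 at P17 and 0.290 at P19. At floor 64, R7 minus R3 early called 62, with 1 list in the mean (neuroblast and Imd and Toll genes lost) and 3 in R7 (neuroblast, haemocyte and disc genes lost).

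Without 2 R3 arrays the counts were 1019 in R3 late minus early, 2770 in the mean, 960 in R3 and 1118 in R7 intermediate minus early, 9 in R3 and 892 in R7 late minus intermediate, 170 and 392 in R7 minus R3 early and intermediate, 563 in both lines, 115 apart and 237 for the R3 slope. The correlation was 0.666, and the mitochondrial respiration list reversed in the mean (adjusted p = 0.0467), where the Notch list was gained (0.0483) and the glycolysis list lost (0.170). Without 3 they were, in the same order, 1064, 2711, 796, 1096, 119 and 926, then 350 for R7 minus R3 intermediate, 586 in both lines, 155 apart and 171 for the R3 slope, with a correlation of 0.666 and 0 lists in the mean (neuroblast, glycolysis and Imd and Toll genes lost).

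Leaving out each array in turn gave 0 to 117 in R3 late minus early, 995 to 2594 in R7, 419 to 2127 in the mean and 136 to 671 in the interaction. It gave 0 to 14 and 128 to 855 in R3 and R7 intermediate minus early, and 0 to 7 and 137 to 645 in late minus intermediate. R7 minus R3 gave 80 to 408 early, 92 to 256 intermediate and 370 to 886 late. Both lines shared 0 to 56, and 29 to 88 were apart. Slopes gave 0 to 151 in R3 and 1179 to 2549 in R7. The correlation ran from -0.148 to 0.642, lists from 3 to 7 in R7 and 2 to 4 in the mean, and the P2 spread from 0.428 to 0.728.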

Other observations

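All tests of single genes in these paragraphs come from the planned comparisons, while the choice of these genes was made after their values were seen.

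Genes of other cell types also moved in R7. The FGF receptor gene btl, a tracheal marker, rose 8.51-fold from early to late, from 73.8 ± 11.7 (SD, n = 3) to 634 ± 146 (n = 3, limma adjusted p = 0.00125). The POU-domain gene vvl, also a tracheal marker, had 282 in R7 early and 1317 in R7 intermediate arrays and fell at least 8.63-fold from early to late arrays. The tracheal list had 1 of 6 members higher and 2 lower and was not called (camera adjusted p = 0.426). Act79B fell 7.96-fold, from 2070 ± 1037 to 243 ± 36.0 (limma adjusted p = 0.000791).

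Sxl, the master gene of female sex determination, was measured in all groups, with means of 854 ± 16.9 (SD, n = 2) in R3 early and 825 ± 83.6 (n = 3) in R7 early arrays. Its change in R7 was -0.23 (log2, limma adjusted p = 0.221).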
